A study of Mus musculus with 39 samples.

How the data were processed

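Faecal pellets of 39 mice were profiled by sequencing of the bacterial 16S rRNA gene. The mice were nmrHAS2 animals, which carry the hyaluronan synthase 2 gene of the naked mole-rat, and CreER controls, each sampled young and old and in both sexes. The labels give conflicting ages: the design text states 7 and 24 months, and the protocol states 9 and 23 months. The groups are therefore called young and old throughout. Per the labels' protocols, the authors extracted DNA with a stool kit, amplified the V1–V2 region over 25 cycles and sequenced paired reads on a MiSeq. The software that made the taxon table and the release of its taxonomy are not given in the sources used here.

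The authors deposited a table of whole-number counts of reads for 581 taxa, each named at 7 ranks. Every one of the 39 mice had a total of exactly 37000 counts, so the deposited counts look subsampled to a common depth, a step that no label or header records. Only 2.31% of the values above 0 lay between 1 and 4, so rare sequences appear to have been removed earlier, and no upper limit was derived from a count of 0. Counts from PCR without molecular identifiers are not independent molecules. On average 52.1% of counts carried no genus name and 92.5% no species name, and unnamed genera are given by the lowest named rank. The group names written in the table matched the sample labels in all 39 mice. Cage, litter and sequencing run are not given in the sources used here, so any of them may coincide with a group. Between 104 and 201 taxa were detected per mouse. No duplicate libraries were seen within groups: over 76 pairs of mice within groups, the lowest chi-square per taxon was 18.3. Pairs of mice from different groups were not compared.

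Relative abundance was computed as the percent of the 37000 counts. The 8 groups of age, genotype and sex were compared in 4 comparisons, genotype within each age and age within each genotype, with the sexes weighted equally. A difference in percent is thus the mean of the differences in females and males, and can depart slightly from the difference of the arm means. Genera, families and phyla were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM factors, robust dispersions and a mean for each of the 8 groups, on taxa with a count of 5 or more in at least 5 mice. Calls were made at a Benjamini-Hochberg false discovery rate of 0.05. The SE printed with an edgeR log2 fold change is its size divided by the square root of the test's F statistic, not a fitted standard error. Single values (phylum and family percent, Shannon diversity with the natural logarithm, the log2 ratio of Firmicutes to Bacteroidetes counts and the share of taxon lists) were compared by two-sided exact permutation tests within sex. Adjusted p-values cover 36 tests for phyla above 0.1% of counts, 32 tests for the 8 most abundant families and 40 tests for lists. Lists were compared as log2(percent + 0.01). Composition was compared by exact permutational analysis of Bray-Curtis dissimilarity at genus level, also within sex. Interactions of single values were tested with 100000 permutations. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 were used for these steps and matplotlib 3.10.9 for figures.

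Because totals are fixed, all values are relative. Against scaling by totals alone, TMM moved the log2 fold change of genera by a median of 0.17 for genotype in old mice, 0.01 for genotype in young mice, -0.13 for age in CreER mice and 0.03 for age in nmrHAS2 mice. For families the medians were 0.31, -0.04, -0.60 and -0.24, and for phyla -0.02, 0.01, -0.30 and -0.34. Fold changes are relative to these shifts, and some single taxa moved further. Where every mouse of a sex group was at 0, the fitted fold change depends on a prior count, and the shares, the number of mice with the taxon and the adjusted p are given without a fold.

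Before the data were examined, the design, 10 taxon lists, the alternatives and the rule for naming taxa were fixed. The rule takes phyla above 0.1% of counts, the 8 most abundant families, up to 10 called genera per direction that were detected in at least 50% of the mice of an arm, and list members that were called or exceeded 1% in an arm. The alternatives were size factors of DESeq2 1.42.0, library totals, no filter or a stricter one (a count of 10 in 10 mice), DESeq2, limma 3.58.1 on centred log ratios, fits of the compared arms alone, fits without sex, a replicate block, other taxonomic levels, other distances and diversity indices, and leaving out each mouse. Tests of family percent, interaction tests of single values, the overlap and correlation of age differences and some fits leaving out a mouse (for sex interactions, families, phyla, lists and the mean percent of genera and lists) were added after the data were seen. Replicate numbers were not taken to pair mice, and pairing was not tested. Within a comparison, 0 to 4 same-number pairs had residuals that correlated above 0.1. The median correlation of same-number pairs ran from -0.083 to 0.027 over the comparisons, and that of other pairs from -0.029 to 0.003. On simulated data for genotype in old mice (20 data sets of 133 genera, 30 of them changed), the edgeR step called 12.0% of genera changed 2-fold, 39.7% of those changed 4-fold and 54.7% of those changed 8-fold with the right sign, and 12.2% of its calls were unchanged genera, above the nominal rate. With no genus changed, 2 of the 20 data sets had a call. The exact test gave p under 0.05 in 5.3% of 1000 simulated data sets without a difference.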

Results

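Faecal communities were compared between nmrHAS2 mice and CreER controls at a young and an old age, to ask whether the gut community of old mice differs with the transgene. There were 5 mice in each group of age, genotype and sex, except 4 old CreER females, which gave 9 old CreER mice and 10 mice in each of the other arms. Each mouse has 37000 counts in the deposited table, and depth before that is not given in the sources used here. Mean Bray-Curtis dissimilarity between mice of an arm lay between 0.240 and 0.268.

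In old mice, nmrHAS2 communities held more Bacteroidetes and Proteobacteria and less Firmicutes and Deferribacteres than CreER communities. Bacteroidetes, anaerobes that break down complex glycans, made up 59.0% ± 6.90 of counts in old nmrHAS2 mice (SD, n = 10) and 48.8% ± 6.11 in old CreER mice (SD, n = 9), a difference of 10.4 points (exact p = 0.00447, adjusted p = 0.0233). Firmicutes made up 30.4% ± 7.21 and 42.8% ± 5.81, a difference of -12.5 points (exact p = 0.00154, adjusted p = 0.0139). For each of these phyla, 9 of 10 nmrHAS2 mice lay on that side of the CreER median. The log2 ratio of Firmicutes to Bacteroidetes was lower by the same comparison, with a difference of -0.80 (exact p = 0.00205) and 9 of 10 nmrHAS2 mice below the CreER median. Proteobacteria reached 6.60% ± 1.40 against 4.33% ± 0.858, and Deferribacteres 0.104% ± 0.124 against 0.626% ± 0.365 (exact permutation tests, adjusted p = 0.00718 and 0.00113). All 10 old nmrHAS2 mice lay beyond the CreER median for both phyla. edgeR called Proteobacteria and Deferribacteres (log2 fold changes 0.57 and -2.96, adjusted p = 0.0174 for both) but not Bacteroidetes (0.24, adjusted p = 0.372) or Firmicutes (-0.51, adjusted p = 0.113). Both edgeR calls were lost without old nmrHAS2 male 2, and that of Proteobacteria also without old CreER female 1 or 2 or old nmrHAS2 female 5 (edgeR adjusted p of up to 0.101, and 0.0579 for Deferribacteres). The exact call of Bacteroidetes was lost without old CreER male 1 or 5 or old nmrHAS2 male 2, with an exact adjusted p of up to 0.0524.

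Among families, Muribaculaceae, the dominant Bacteroidetes family of mice, made up 40.6% ± 8.46 of counts in old nmrHAS2 mice and 29.7% ± 5.24 in old CreER mice (exact adjusted p = 0.0185). Burkholderiaceae were also higher, at 4.55% ± 1.40 against 1.99% ± 0.574 (exact adjusted p = 0.00134). Lachnospiraceae, Ruminococcaceae and the Clostridiales vadinBB60 group, families of Clostridia, were lower by exact tests, with differences of -8.48, -4.07 and -1.11 points (adjusted p = 0.0168, 0.0169 and 0.0126), but edgeR did not call them (adjusted p = 0.433, 0.860 and 0.421). These differences were seen, relative to the CreER median, in 9 of 10 nmrHAS2 mice for Muribaculaceae, 8 for the vadinBB60 group and all 10 for the others. Rikenellaceae, Prevotellaceae and Bacteroidaceae differed by -1.46, 0.228 and 0.351 points, none past the threshold.

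At genus level, edgeR called 4 of 133 genera between old genotypes, 1 higher and 3 lower in nmrHAS2 mice (2 higher and 3 lower with library totals). Parasutterella, an asaccharolytic member of Burkholderiaceae, was higher with a log2 fold change of 1.40 ± 0.33 (SE, adjusted p = 0.0171), at 4.52% ± 1.40 against 1.92% ± 0.604, and all 10 nmrHAS2 mice exceeded the CreER median. Mucispirillum, a mucus-dwelling genus and the member of Deferribacteres found here, was lower with a log2 fold change of -2.75 ± 0.80 (SE, adjusted p = 0.0491) and was detected in 6 of 10 nmrHAS2 mice and all 9 CreER mice. The Lachnospiraceae genus A2 was also lower, with a log2 fold change of -1.26 ± 0.33 (SE, adjusted p = 0.0342), and for both genera all 10 nmrHAS2 mice lay below the CreER median. An unnamed genus of Enterobacteriaceae was detected in 5 of 9 CreER mice, at a mean of 0.0598% (0.0338% without old CreER female 3), and in 0 of 10 nmrHAS2 mice (adjusted p = 0.0403). Parasutterella was called without each of the 19 mice in turn, A2 in 14, the Enterobacteriaceae genus in 8 and Mucispirillum in 7 of these 19 fits, and limma on centred log ratios called only Mucispirillum. Mucispirillum was not called by fits of the compared arms alone (adjusted p = 0.0706) or without sex (adjusted p = 0.0541), nor A2 without a count filter (adjusted p = 0.474). At family level edgeR called 3 higher (Muribaculaceae, Burkholderiaceae and Lactobacillaceae) and 1 lower (Deferribacteraceae), and 1 higher and 1 lower with library totals, where Muribaculaceae did not pass (log2 fold change 0.45, adjusted p = 0.111, against 0.80 and 0.0312). Of the 19 fits that left out a mouse, Burkholderiaceae kept the call in 18, Muribaculaceae in 10, Deferribacteraceae in 6 and Lactobacillaceae in 3.

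**Figure D1:**
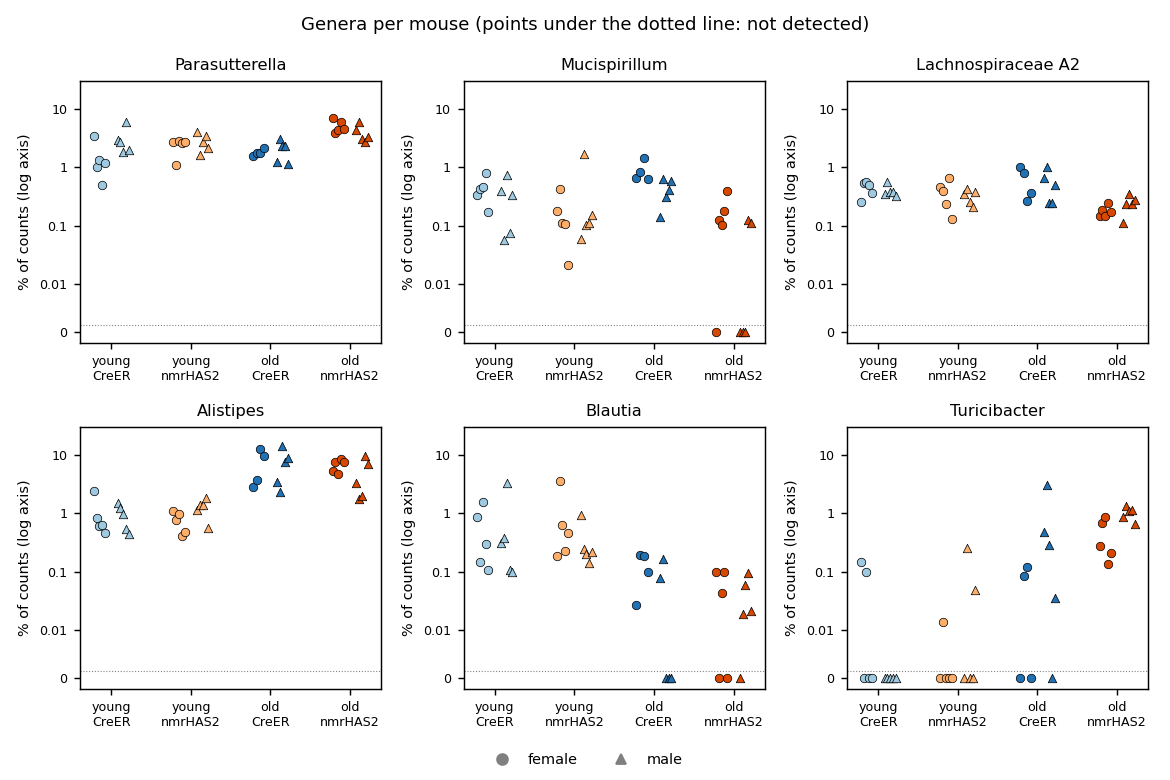
Relative abundance of 6 genera in each mouse, as percent of counts on a log axis, by age and genotype. Circles are females, triangles are males and points under the dotted line were not detected; Parasutterella was highest on average in old nmrHAS2 mice (4.52%), where Mucispirillum was lowest (0.104%).

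Of the taxon lists, 6 differed between old genotypes by exact tests, each with 9 or 10 of the 10 nmrHAS2 mice on the side of the difference. The butyrate-producing genera were lower, at 8.04% ± 3.74 against 13.8% ± 4.53 of counts (log2 difference -0.90, adjusted p = 0.0422). Its most abundant member, the Lachnospiraceae NK4A136 group, averaged 5.08% against 9.11%, Oscillibacter 1.24% against 2.13%, and Odoribacter 0.943% against 1.10%; of 6 tested members 0 passed, either over all genera or adjusted over the list alone. Clostridia families were lower (log2 difference -0.62, adjusted p = 0.0298) and Bacteroidales families higher (0.28, adjusted p = 0.0298), the latter with 1 of 6 tested families passing, Muribaculaceae, both over all families and adjusted over the list alone. The lactic acid bacteria and bifidobacteria were higher (log2 difference 0.96, adjusted p = 0.0373), almost entirely as Lactobacillus, at 0.930% ± 0.365 against 0.502% ± 0.303. Lactobacillus, the 1 member tested, passed adjusted over the list alone but not over all genera. The Erysipelotrichia genera were higher, at means of 0.948% ± 0.673 against 0.545% ± 1.10 (log2 difference 2.63, exact adjusted p = 0.0298). The old CreER mean was 0.184% without old CreER male 2, at 3.43%, and the medians were 0.773% and 0.197%. The log2 difference depends on the 0.01 added to percents at or near 0: it was 1.57 with 0.1 added, and the difference in percent, 0.447 points, did not pass (exact adjusted p = 0.542). Turicibacter was detected in all 10 nmrHAS2 mice and 6 of 9 CreER mice, although 0 of 3 tested members passed over all genera or adjusted over the list alone, as was true of the 6 Clostridia families.

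The list of inflammation-associated genera was higher in old nmrHAS2 mice (log2 difference 0.41, adjusted p = 0.0422), but its members moved apart. Of 9 tested members, 1 was higher (Parasutterella) and 1 lower (Mucispirillum) over all genera, and 2 were higher and 2 lower adjusted over the list alone, with Proteus and the bile-tolerant Bilophila added. Proteus was rare, found in 4 of 10 nmrHAS2 mice, at a mean of 0.0116%, and in 0 of 9 CreER mice. Bilophila averaged 0.125% in old nmrHAS2 and 0.466% in old CreER mice. Parasutterella, a common resident of the healthy gut, made up 4.52% of the list's 5.43% in old nmrHAS2 mice and 1.92% of its 4.04% in old CreER mice. The mucus-associated genera did not pass as a whole (log2 difference 0.02, exact adjusted p = 0.956): Mucispirillum was lower, while Bacteroides averaged 3.73% against 3.42%. The log2 difference of this list averages the sexes, and that of females minus that of males was -1.11. This difference between the sexes did not pass over 87 interaction tests (permutation p = 0.00252, adjusted p = 0.219). Akkermansia did not pass (edgeR adjusted p = 0.973) and averaged 0.123% against 0.493% in females and 2.17% against 0.408% in males, with medians of 0.123% and 0.1% over both sexes. Its mean of 1.15% over old nmrHAS2 mice was 0.674% without old nmrHAS2 male 3. The butyrate list lost its call without any of 13 of the 19 mice, the inflammation list without any of 12 and the list of lactic acid bacteria and bifidobacteria without any of 6, with an exact adjusted p of up to 0.112, 0.112 and 0.0721. Compared as percent without a logarithm, neither the inflammation list nor the lactic list passed (exact adjusted p = 0.0675 and 0.0591), and without sex strata those lists and the butyrate and Erysipelotrichia lists did not pass. Sulphate-reducing bacteria, plant organelle sequence and reagent and skin genera did not pass (log2 differences -0.51, 0.79 and -0.57), and of their members 0 passed over all genera, while Bilophila and the chloroplast taxon passed adjusted over the list alone.

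Community composition differed between old genotypes, with genotype taking 0.215 of the Bray-Curtis variation (R2, exact p = 0.00463). With Jaccard distance, which uses only presence, R2 was 0.0641 (exact p = 0.161). Shannon diversity was 3.41 ± 0.199 in old nmrHAS2 mice and 3.58 ± 0.131 in old CreER mice, a difference of -0.168 (exact p = 0.0482). This call was lost when any of 14 of the 19 mice was left out, with the inverse Simpson index (exact p = 0.127) and at genus level (exact p = 0.117).

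**Figure D2:**
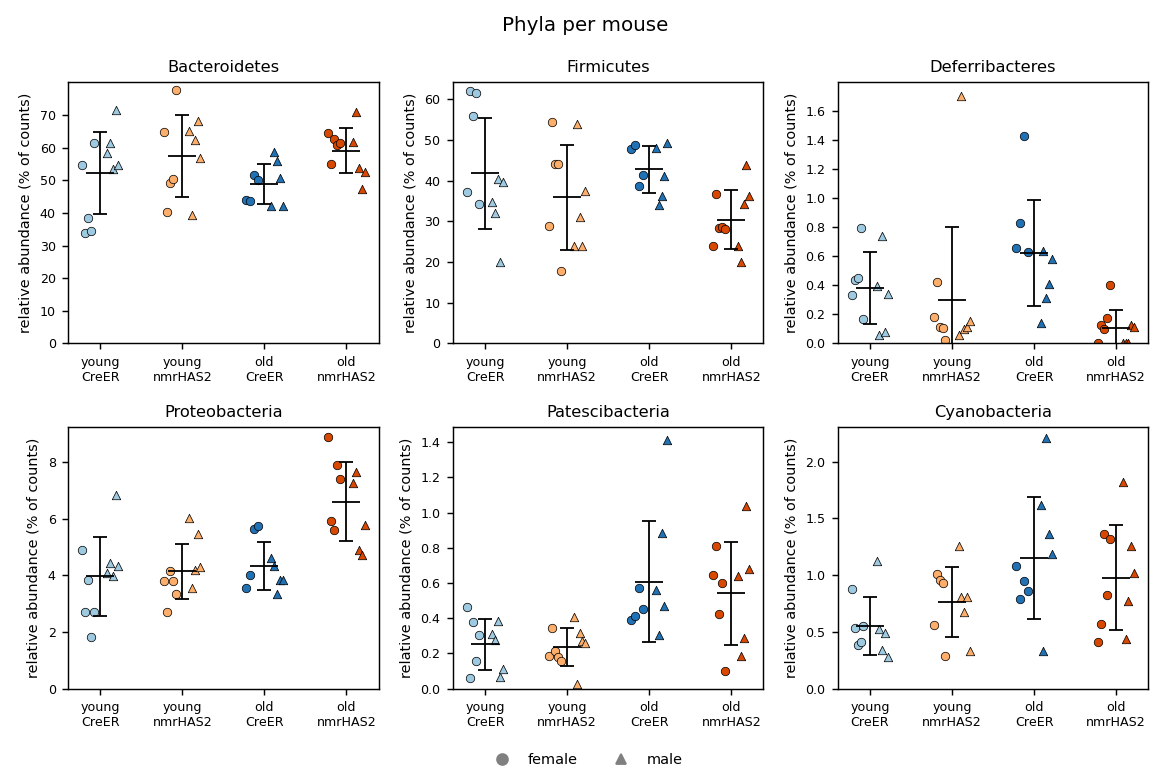
Relative abundance of 6 phyla in each mouse, as percent of counts, by age and genotype, with circles for females, triangles for males and bars for the mean ± SD. Deferribacteres averaged 0.104% in old nmrHAS2 mice and 0.626% in old CreER mice, and Proteobacteria 6.60% and 4.33%.

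In young mice of both sexes together, edgeR over all genera, families and phyla and the exact tests called no difference between genotypes, while some alternatives called a few genera. In females alone, edgeR called the Ruminococcaceae NK4A214 group, found in 3 of 5 nmrHAS2 and 0 of 5 CreER females (edgeR adjusted p = 0.0327). Bacteroidetes averaged 57.4% ± 12.5 in young nmrHAS2 mice and 52.2% ± 12.6 in young CreER mice (SD, n = 10 each), and Firmicutes 35.9% ± 12.9 and 41.7% ± 13.7. In females Bacteroidetes averaged 56.5% against 44.6% and Firmicutes 37.8% against 50.1%. In males Bacteroidetes averaged 58.3% against 59.9% and Firmicutes 34.0% against 33.3%. The sex-by-genotype difference did not pass for either phylum (permutation adjusted p = 0.806 for both). Over both sexes, Parasutterella averaged 2.60% against 2.30%, and Mucispirillum 0.298% against 0.380%. The Mucispirillum mean in young nmrHAS2 mice was 0.141% without young nmrHAS2 male 2, the medians were 0.112% and 0.368%, and 8 of 10 nmrHAS2 mice lay below the CreER median (edgeR log2 fold change -0.56, adjusted p = 0.9998). Genotype took 0.0478 of the Bray-Curtis variation (R2, exact p = 0.374), and Shannon diversity differed by -0.0663 (exact p = 0.713). edgeR called 0 genera, with 10 at an unadjusted p under 0.05, DESeq2 called 2, edgeR without a count filter 2 and limma on centred log ratios 0, and edgeR called 1 taxon at species level. It called 0 families, with 4 at an unadjusted p under 0.05, and 0 phyla, with 0 at that level; limma on centred log ratios called 0 of each. None of the 10 lists passed, the lowest exact adjusted p being 0.125 for Erysipelotrichia genera, where 1 of 3 tested members, Erysipelatoclostridium, passed adjusted over the list alone and 0 over all genera.

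The genotype difference was not shown to change with age. For the age-by-genotype interaction, edgeR called 0 genera, with 14 at an unadjusted p under 0.05, DESeq2 called 2 and limma on centred log ratios 0. Among 87 interaction tests of single values, the age-by-genotype test gave p = 0.0134 for Proteobacteria and 0.0135 for Burkholderiaceae in permutation tests, with an adjusted p of 0.391 for both. Old nmrHAS2 mice lay 0.317 ± 0.0456 in Bray-Curtis dissimilarity from young CreER mice of their own sex, and old CreER mice 0.306 ± 0.0378, a difference of 0.0136 (exact p = 0.491).

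In CreER mice, old communities held less Muribaculaceae and more Rikenellaceae than young ones. Muribaculaceae fell from 42.3% ± 11.9 (SD, n = 10) to 29.7% ± 5.24 (SD, n = 9), and all 9 old mice lay below the young median of both sexes together (exact adjusted p = 0.0185). The fall was larger in males, from 49.8% to 30.2%, than in females, from 34.8% to 29.1%, and its dependence on sex was not tested. The old CreER mice are the same animals in this comparison and in that of old genotypes, so the 2 Muribaculaceae differences share their chance values. Rikenellaceae, bile-tolerant Bacteroidales, rose from 3.26% ± 0.625 to 9.42% ± 4.24 (exact adjusted p = 0.00101), and the Clostridiales vadinBB60 group rose by 1.32 points (exact adjusted p = 0.0063), though edgeR did not call it (0.13, adjusted p = 0.824, and 0.79, adjusted p = 0.0235 with library totals). Cyanobacteria, which in the gut are mostly non-photosynthetic relatives, rose by 0.578 points and Patescibacteria by 0.341 points (exact adjusted p = 0.0233 and 0.0141), in 8 and 9 of the 9 old mice, and edgeR called neither (log2 fold changes 0.74 and 1.00, adjusted p = 0.0736 and 0.394). The Cyanobacteria call was lost without young CreER male 2, 3, 4 or 5, with an exact adjusted p of up to 0.0567. Rikenellaceae and the vadinBB60 group exceeded the young median in all 9. Bacteroidetes and Firmicutes as phyla differed by -3.60 and 1.18 points, neither past the threshold, and the log2 ratio of the pair by 0.17 (exact p = 0.549). These values average opposite directions in the sexes, a contrast that was not tested. From young to old, Bacteroidetes went from 44.6% to 47.3% in females and from 59.9% to 49.9% in males. Firmicutes went from 50.1% to 44.1% in females and from 33.3% to 41.7% in males.

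At genus level, edgeR called 10 genera with age in CreER mice, 8 higher and 2 lower in old mice (8 higher and 8 lower with DESeq2 size factors). Alistipes, a genus of Rikenellaceae, rose from 0.954% ± 0.609 to 7.23% ± 4.38, with a log2 fold change of 2.89 ± 0.38 (SE, adjusted p = 3.59e-07), and all 9 old mice exceeded the young median. Rikenella of the same family fell, at -1.04 ± 0.32 (SE, adjusted p = 0.0333, and 0.0584 with library totals). Ruminococcaceae UCG-014 rose (log2 fold change 1.61 ± 0.41, SE, adjusted p = 0.0115), and Blautia, an acetate-producing Lachnospiraceae genus, fell (-3.13 ± 0.99, SE, adjusted p = 0.0413). The Christensenellaceae R-7 group was found in 9 of 9 old and 1 of 10 young mice (adjusted p = 0.00112) and the Ruminococcaceae NK4A214 group in 9 of 9 and 3 of 10 (adjusted p = 0.0115). The NK4A214 group averaged 0.152% in old females and was found in 0 of 5 young females, while males averaged 0.144% in old and 0.129% in young (log2 fold change -0.08, adjusted p = 0.985). Turicibacter was found in 6 of 9 and 2 of 10, an unnamed genus of Gastranaerophilales in 8 of 9 and 3 of 10, and unnamed genera of Flavobacteriaceae and Peptostreptococcaceae each in 5 of 9 old mice, against 0 and 1 of 10 young mice (adjusted p = 0.0115, 0.0333, 0.0139 and 0.0139). Turicibacter was found in 4 of 5 old and 0 of 5 young males, while females averaged 0.0514% in old and 0.0492% in young (log2 fold change 0.29, edgeR adjusted p = 1). Its mean of 0.448% over old CreER mice was 0.125% without old CreER male 2. The Gastranaerophilales genus was found in 4 of 5 old and 0 of 5 young males, and in 4 of 4 old and 3 of 5 young females. Whether these age differences depend on sex was not tested. The Flavobacteriaceae call was lost without old CreER female 3 and the Peptostreptococcaceae call without old CreER female 2. Of the 19 fits that left out a mouse, the Gastranaerophilales genus and Blautia each lost their call in 5 and Rikenella in 2, with adjusted p of up to 0.066, 0.114 and 0.0748. A fit without sex did not call the NK4A214 group or the Gastranaerophilales genus, and limma on centred log ratios called Alistipes, Rikenella, Blautia, the R-7 group and the NK4A214 group but none of the other 5.

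edgeR called 15 families with age in CreER mice, 8 higher and 7 lower, against 13 higher and 2 lower with library totals. The lower calls included Lachnospiraceae and Ruminococcaceae (log2 fold changes -0.76 and -0.71), whose percent of counts differed by only -0.805 and -0.375 points (exact p = 0.8 and 0.864). With library totals the log2 fold changes were -0.03 and 0.02, so these calls depend on the TMM scaling. It called 0 phyla, with 3 at an unadjusted p under 0.05, while limma on centred log ratios called 1. Age took 0.231 of the Bray-Curtis variation (R2, exact p = 9.45e-05). Shannon diversity rose from 3.16 ± 0.243 to 3.58 ± 0.131 (difference 0.421, exact p = 0.000346), with all 9 old mice above the young median. Of the lists, only the mucus-associated genera passed (log2 difference 0.89, exact adjusted p = 0.0258), in all 9 old mice, with 0 of 4 tested members passing over all genera or adjusted over the list alone; Bacteroides averaged 3.42% in old and 1.95% in young mice. Of the Erysipelotrichia genera, 1 of 3 tested members rose over all genera, and 2 adjusted over the list alone.

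**Figure D3:**
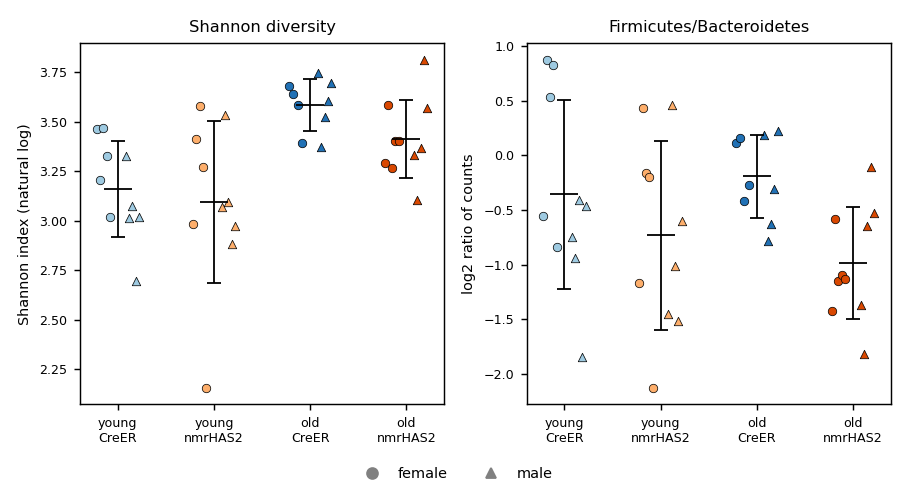
Shannon diversity (natural logarithm) and the log2 ratio of Firmicutes to Bacteroidetes counts in each mouse, by age and genotype, with circles for females, triangles for males and bars for the mean ± SD. Mean Shannon diversity was 3.58 in old and 3.16 in young CreER mice, and 3.41 in old and 3.09 in young nmrHAS2 mice.

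In nmrHAS2 mice, old communities also held more Rikenellaceae, which rose from 3.21% ± 0.803 to 7.94% ± 2.65 (SD, n = 10 each, exact adjusted p = 0.00134). Proteobacteria rose from 4.14% ± 0.974 to 6.60% ± 1.40 (exact adjusted p = 0.00718), and Burkholderiaceae by 1.93 points (exact adjusted p = 0.00887). The old nmrHAS2 mice are the same animals here and in the comparison of old genotypes. Differences of the same taxon or list in both comparisons therefore share chance values. Patescibacteria rose by 0.306 points (exact adjusted p = 0.0322), a call lost without any of 12 of the 20 mice. edgeR did not call Proteobacteria, Burkholderiaceae or Patescibacteria (log2 fold changes 0.29, 0.51 and 0.82, adjusted p = 0.303, 0.195 and 0.467), while with library totals Proteobacteria and Burkholderiaceae passed (0.68 and 0.79, adjusted p = 0.000328 and 0.0367). Relative to the young median, these differences held in 9 of 10 old mice for Rikenellaceae and Burkholderiaceae, 10 for Proteobacteria and 8 for Patescibacteria. Muribaculaceae averaged 46.7% ± 12.6 in young and 40.6% ± 8.46 in old mice, a difference of -6.11 points that did not pass (exact adjusted p = 0.413), although 9 of 10 old mice lay below the young median. In edgeR its log2 fold change of -0.56 passed adjusted over the Bacteroidales list alone (adjusted p = 0.0461) but not over all families (adjusted p = 0.0768), and was -0.21 with library totals (adjusted p = 0.363 over all families). Of the list's 6 tested families, Rikenellaceae was the 1 that was higher, both over all families and adjusted over the list alone. The log2 ratio of Firmicutes to Bacteroidetes differed by -0.25 (exact p = 0.449).

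edgeR called 13 genera with age in nmrHAS2 mice, 9 higher and 4 lower in old mice (8 higher and 10 lower with DESeq2 size factors). Alistipes rose from 0.996% ± 0.454 to 5.72% ± 2.76 (log2 fold change 2.54 ± 0.37, SE, adjusted p = 3.74e-06), and Turicibacter from 0.0316% ± 0.0796 (0.00691% without young nmrHAS2 male 2) to 0.724% ± 0.415 (5.75 ± 1.32, SE, adjusted p = 0.00396). An unnamed genus of Erysipelotrichaceae also rose (1.60 ± 0.52, SE, adjusted p = 0.0384, and 0.0633 with DESeq2 size factors). Blautia fell (-3.71 ± 0.97, SE, adjusted p = 0.0105), as did Ruminiclostridium 9 (-0.68 ± 0.21, SE, adjusted p = 0.0306). The Christensenellaceae R-7 group was found in 10 of 10 old and 1 of 10 young mice (edgeR adjusted p = 0.00136). The unnamed Peptostreptococcaceae genus was found in 9 and 1 (adjusted p = 0.00245), and Coriobacteriaceae UCG-002 in 9 and 3 (adjusted p = 0.0306). The 3 young mice with UCG-002 were males. Its mean over all 5 males of an age was 0.0632% in young and 0.123% in old mice. Clostridium sensu stricto 1 and the unnamed Flavobacteriaceae genus were each found in 5 of 10 old and 0 of 10 young mice (adjusted p = 0.014 and 0.0107), and Erysipelatoclostridium in 0 of 10 old and 5 of 10 young mice (adjusted p = 0.0105). Outside the naming rule, and chosen after their values were seen, Rothia was found in 3 old and 0 young mice and Negativibacillus in 0 old and 4 young mice (adjusted p = 0.0384 and 0.0306). Of the 20 fits that left out a mouse, the Erysipelotrichaceae genus lost its call in 9 (adjusted p up to 0.126), Rothia in 12, Coriobacteriaceae UCG-002 in 4, Ruminiclostridium 9 in 3 and Negativibacillus in 1. A fit without sex did not call Coriobacteriaceae UCG-002 or Ruminiclostridium 9, and limma on centred log ratios did not call Coriobacteriaceae UCG-002, the Flavobacteriaceae genus or Rothia.

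edgeR called 9 families, 7 higher and 2 lower, against 8 higher and 0 lower with library totals, and 1 phylum, lower, against 1 higher with library totals. The phylum was Firmicutes, with a log2 fold change of -0.70 (adjusted p = 0.0271), although its percent of counts differed by -5.55 points, which did not pass (exact adjusted p = 0.46). With library totals its log2 fold change was -0.24 (edgeR adjusted p = 0.359), and the call was lost in 15 of the 20 fits that left out a mouse. Age took 0.223 of the Bray-Curtis variation (R2, exact p = 0.000189). Shannon diversity rose from 3.09 ± 0.41 to 3.41 ± 0.199 (difference 0.319, exact p = 0.034), a call lost in 9 of the 20 fits that left out a mouse. Of the lists, mucus-associated genera (log2 difference 0.64, exact adjusted p = 0.0329), inflammation-associated genera (0.49, exact adjusted p = 0.0298) and Erysipelotrichia genera (3.19, exact adjusted p = 0.00504) rose, in 8, 10 and 10 of 10 old mice. Erysipelotrichia genera averaged 0.948% ± 0.673 in old and 0.157% ± 0.159 in young mice, and their log2 difference was 2.03 with 0.1 added in place of 0.01. The mucus list lost its call without old or young nmrHAS2 female 5, and without sex strata. Parasutterella, the main member of the inflammation list, averaged 4.52% in old and 2.60% in young mice, and 0 of that list's 9 and of the mucus list's 4 tested members passed over all genera or adjusted over the list alone. Of the 3 tested Erysipelotrichia genera, 1 rose and 1 fell over all genera, and 2 rose and 1 fell adjusted over the list alone.

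The age differences of both genotypes, which share no mice, overlapped. Of 8 genera higher with age in CreER mice and 9 in nmrHAS2 mice, 5 were shared, where independent lists would share 0.541 (one-sided Fisher's exact p = 2.03e-05): Alistipes, Turicibacter, the Christensenellaceae R-7 group and the unnamed genera of Flavobacteriaceae and Peptostreptococcaceae. Blautia was the 1 shared genus among those lower with age (one-sided Fisher's exact p = 0.0595). Both Fisher tests treat genera as independent and equally likely to be called. The lists of both genotypes came from the same fit with shared estimates of spread, so these p-values are only a rough guide. Across the 90 genera detected in all 8 groups, log2 fold changes with age correlated between genotypes (Pearson r = 0.726, Spearman rho = 0.596), where genera are not independent replicates.

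**Figure D4:**
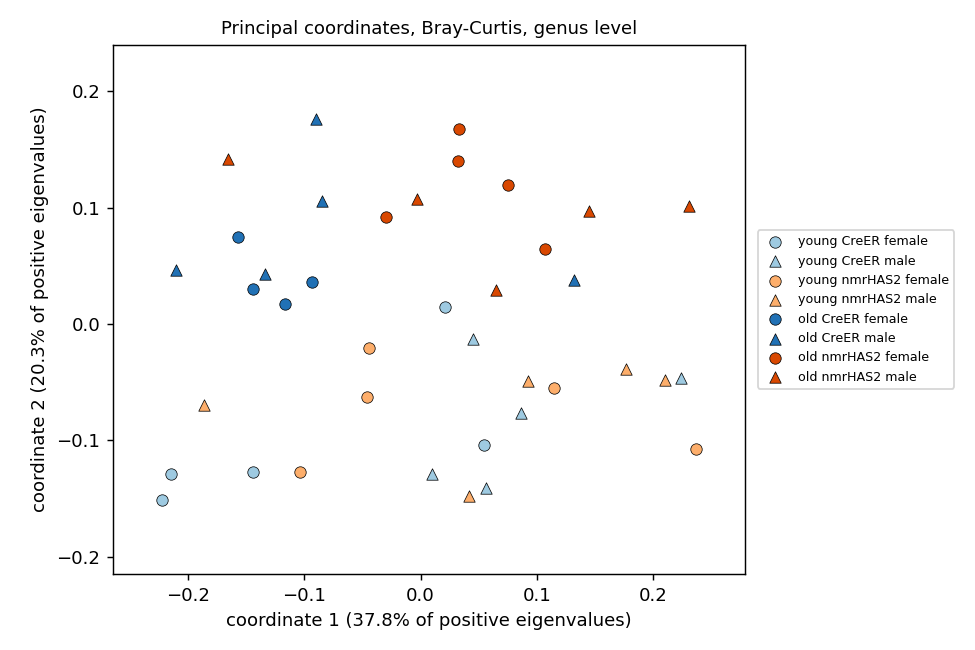
Principal coordinates of Bray-Curtis dissimilarity at genus level, with a point for each of 39 mice, circles for females and triangles for males. Coordinate 1 holds 37.8% and coordinate 2 holds 20.3% of the positive eigenvalues, and the old mice lie at 0.0176 or above on coordinate 2, where the highest young mouse lies at 0.0149.

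Few differences between the sexes in the genotype effect passed the threshold. Among the 87 interaction tests of single values, the lowest p was for mucus-associated genera between the sexes of old mice (permutation p = 0.00252, adjusted p = 0.219). In old mice, edgeR called 0 genera for the sex-by-genotype interaction, with 5 at an unadjusted p under 0.05, and limma on centred log ratios also called 0. In young mice edgeR called 3, 1 higher and 2 lower in females relative to males: the Ruminococcaceae NK4A214 group, Turicibacter and the Christensenellaceae R-7 group (adjusted p = 0.0136, 0.0236 and 0.0163). Each was absent from at least 1 of the 4 young groups and was found in at most 3 of 5 mice of any of them, and limma on centred log ratios called 0. The R-7 group was found in only 1 of 5 young CreER females and 1 of 5 young nmrHAS2 males.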

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

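The test of Mucispirillum within each sex was chosen after its values by sex were seen.

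Single mice stood apart from others of their age, genotype and sex in 20 of 241 tests of a gap against the group's range. Independent values from a normal distribution would give about 1 in 20, or 12.1. The measures overlap and some were 0 in most mice of a group, so 12.1 is only a rough guide to chance. Shares of single mice are given with Wilson 95% intervals, which cover counting error only. Young nmrHAS2 male 1 had 201 detected taxa, against 125 to 146 in the other males of its group. Young nmrHAS2 male 2 had 1.70% Deferribacteres (1.58 to 1.84), against at most 0.154%, with 28.2% Muribaculaceae (27.8 to 28.7), below the 49.0% to 55.8% of the others, and 20.4% Ruminococcaceae (19.98 to 20.8), above 12.1%. Young CreER male 4 had 6.85% Proteobacteria (6.60 to 7.11), 6.07% Burkholderiaceae (5.83 to 6.32) and 6.87% inflammation-associated genera (6.61 to 7.13), above the others' 4.45%, 2.99% and 4.11%. Young CreER male 1 had 5.98% mucus-associated genera (5.74 to 6.22), above 2.76%. Young CreER female 1 had 3.51% Burkholderiaceae (3.33 to 3.70) and 3.03% Bacteroidaceae (2.86 to 3.21), above 1.39% and 1.32%. Young nmrHAS2 female 1 had 0.662% Verrucomicrobia (0.584 to 0.750), above 0.138%, and female 2 had 1.08% Burkholderiaceae (0.978 to 1.19), below 2.65%.

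Old nmrHAS2 female 2 had 15.6% Lachnospiraceae (15.2 to 16.0) and 10.8% butyrate-producing genera (10.5 to 11.1), above 12.6% and 7.6%. Old CreER female 1 had 0.235% lactic acid bacteria and bifidobacteria (0.191 to 0.290), below 0.416%, and old CreER male 4 had 0.0243% reagent and skin genera (0.0128 to 0.0462), below 0.159%. Plant organelle sequence reached 0.0865% (0.0613 to 0.122) in old nmrHAS2 female 1, 0.0649% (0.0436 to 0.0965) in young CreER female 1, 0.165% (0.128 to 0.212) in young nmrHAS2 female 4 and 0.0595% (0.0393 to 0.0900) in young nmrHAS2 male 1. The other mice of the 3 female groups were at 0 and those of the male group at most at 0.00541%.

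For genotype in young mice, edgeR called a difference between the sexes in the Christensenellaceae R-7 group, the Ruminococcaceae NK4A214 group and Turicibacter (adjusted p = 0.0163, 0.0136 and 0.0236). The R-7 call rests on 1 of 5 young CreER females and 1 of 5 young nmrHAS2 males, the only young mice with that genus. When the mice were regrouped at random, 11 of 100 splits, the real one included, gave 3 or more genera and the highest other split gave 7, so chance is not excluded for this count.

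For genotype in old mice, 1 of 100 splits, the real one included, gave the 4 genera seen, and the highest other split gave 3. For families 2 of 100 splits gave the 4 seen (highest other 4), and for phyla 2 of 100 gave the 2 seen (highest other 3), so a random division of the mice is excluded as the source of these counts at a share of 0.05. With age in CreER mice, 1 of 100 splits gave the 10 genera (highest other 3) and 1 of 100 the 15 families (highest other 4), and in nmrHAS2 mice 1 of 100 gave the 13 genera (highest other 2) and 1 of 100 the 9 families (highest other 7). The single phylum called with age in nmrHAS2 mice was matched by 18 of 100 splits (highest other 3). Counts of 0, for genera, families and phyla between young genotypes, phyla with age in CreER mice and genera in the age-by-genotype and old sex-by-genotype interactions, are matched by all 100 splits; the highest other splits gave 7, 9, 2, 1, 6 and 1.

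Mucispirillum was lower in old nmrHAS2 than in old CreER mice. Dilution by taxa that grew in the closed sum would lower other genera alike. The test took the 106 other genera detected in every old group of genotype and sex. With library totals their median log2 fold change was -0.20, against -2.80 for Mucispirillum, and 0 of the 106 fell further. Genera absent from a group were left out beforehand. Among them was the unnamed genus of Enterobacteriaceae, found in 5 of 9 CreER and 0 of 10 nmrHAS2 mice. A difference in 1 sex only is also excluded, since the larger exact p of the sexes was 0.0159 (log2 differences -3.03 in females and -3.78 in males). Genotype, which the design names, stays open, as do cage and litter, which are not given in the sources used here.

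Shannon diversity was higher in old than in young CreER mice. The listed reagent and skin genera and the phyla under 0.1% of counts on average were not the source. Without these 63 taxa, at most 1.12% of counts in a mouse, the difference was 0.418 (exact p = 0.000315). These taxa need not come from outside the gut, and outside sequence among other taxa was not examined. Without the most abundant genus, an unnamed genus of Muribaculaceae with a mean of 29.2% of counts, the difference fell to 0.175 (exact p = 0.113). The rise may therefore reflect in part the share of that genus, which edgeR did not call with age in CreER mice. Removing so abundant a genus can itself change Shannon diversity, and no other genus was removed for comparison. Age, which the design names, and cage stay open as reasons for the rise.

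Some mice had many more detected taxa than others. Across 39 mice, the number of detected reagent and skin genera rose with the number of other detected taxa (Pearson r = 0.621, permutation p = 5e-05; Spearman rho = 0.611, permutation p = 6e-05; both adjusted p = 6e-05), and r was 0.552 without the 2 mice farthest from the median. Within arms r was 0.344 in old CreER and 0.392 in old nmrHAS2 mice, and 0.707 and 0.882 in young CreER and young nmrHAS2 mice. Sequence from outside the gut may add to the number of detected taxa, but these correlations cannot show it. Rare genera of any kind could rise with the number of other taxa, and no other set of them was compared. The genera of that list can also live in the gut. No biological explanation was tested.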

How the results depend on the processing

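Leaving out each mouse was chosen after seeing the data for sex interactions, families, phyla, lists and the mean percent of genera and lists, while the other alternatives were planned. Apart from those fits, the values that answer a comparison kept their direction and side of the threshold, or a count within 1.5 times, in 83 cases, while counts moved further in 29, calls were lost in 5 and the sign changed in 2. The cause was not tested unless stated. The Firmicutes to Bacteroidetes ratio in old mice and the distance to young CreER mice kept their side of the threshold in every setting. Bray-Curtis R2 did so except with the Jaccard distance, where R2 between old genotypes was 0.0641 (exact p = 0.161). R2 between young genotypes and the distance to young CreER mice had not passed in the main tests (exact p = 0.374 and 0.491). A mean over 100 rarefactions was not run separately, since all totals are equal and rarefying to the lowest changes nothing.

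Counts of genera are given in the order genotype in old mice, genotype in young mice, age in CreER mice and age in nmrHAS2 mice, where the main counts were 4, 0, 10 and 13. Without a count filter they were 7, 2, 20 and 14, with DESeq2 10, 2, 20 and 23, with limma on centred log ratios 1, 0, 11 and 29, and at species level, where more taxa are tested, 8, 1, 44 and 45. With replicate number as a block they were 1, 0, 5 and 4. DESeq2 size factors and a fit without sex gave 16 and 21 genera with age in CreER mice, and the stricter filter 7 with age in nmrHAS2 mice. The age-by-genotype interaction gave 4 genera without a filter and 2 with DESeq2, and the young sex-by-genotype interaction 11 without a filter and 0 with limma on centred log ratios. Library totals gave 2 families between old genotypes and 1 phylum with age in CreER mice. On centred log ratios, limma gave 6 families and 1 phylum with age in CreER mice and 1 phylum between old genotypes.

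Of Shannon differences, that between old genotypes was -0.110 at genus level (exact p = 0.117), -2.62 as inverse Simpson (exact p = 0.127) and 0 as observed taxa (exact p = 1). Observed taxa differed by 6.60 between young genotypes, with the sign reversed (exact p = 0.536), and by 16.3 with age in nmrHAS2 mice (exact p = 0.11). With medians, the log2 Firmicutes to Bacteroidetes ratio differed by -0.087 with age in CreER mice, with the sign reversed (exact p = 0.808). Of lists, 3 others that had not passed changed sign: sulphate-reducing bacteria with age in CreER mice without sex strata (-0.078), and on percent, Clostridia families with age in CreER mice (-0.878) and lactic acid bacteria and bifidobacteria between young genotypes (-0.102). Without sex strata, 5 list differences passed in place of 10.

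Leaving out a mouse gave 1 to 7 genera between old genotypes: 1 without old CreER female 1 or 2, male 2 or 5 or old nmrHAS2 female 1, 2 without old nmrHAS2 male 2 or 3, and 7 without old CreER male 3. With age in CreER mice it gave 9 to 17 genera (17 without old CreER male 4, 16 without young CreER female 1 or 5), and 2 to 5 for the young sex-by-genotype interaction (5 without young CreER female 5 or young nmrHAS2 male 1). Families numbered 1 to 6 between old genotypes, 0 to 1 between young genotypes, 6 to 16 with age in CreER mice (6 without old CreER female 2) and 5 to 14 with age in nmrHAS2 mice (5 without old nmrHAS2 female 4, 14 without young nmrHAS2 male 1). Phyla numbered 0 to 2, 0 to 2 and 0 to 3 between old genotypes and with age in CreER and in nmrHAS2 mice. The Shannon difference ranged from -0.215 to -0.127 between old genotypes, from 0.203 to 0.381 with age in nmrHAS2 mice and from -0.129 to 0.0491 between young genotypes, with the sign reversed without young nmrHAS2 female 5. Of 27 genus calls, where a genus called in both age comparisons counts in each, 16 stayed past the threshold with limma on centred log ratios, 24 with DESeq2, 22 without a filter and 26 with library totals; 10 stayed with the replicate block.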

Other observations

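The test of shared carriage was chosen after the values by sex were seen. Several genera were detected in nearly all mice of a group and in few of another of the same age, which cage mates sharing bacteria could produce. Over 44 genera, the mean share of detection variance between groups of one age, genotype and sex was 0.271, against a median of 0.267 when mice were permuted 10000 times (permutation p = 0.393). Carriage shared within these groups was thus not borne out, although cages are not given in the sources used here and need not follow the groups.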
